A study of Mus musculus with 2 samples.

How the data were processed

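H3K27me3, the repressive histone mark that Polycomb repressive complex 2 deposits, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse limb at embryonic day 15.5. The series holds 1 group of 2 biological replicates from strain B6NCrl, each a pool of embryos of both sexes. Replicate 1 came from the limbs of 78 embryos and replicate 2 from those of 62, and each biological replicate joined 2 technical replicates. Fragments were selected between 300 and 500 bp, per the labels. The tissue was healthy per the labels, and no other stage, tissue or treatment is among the samples, so no contrast between conditions was possible.

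The deposited data were 4 lists of peaks in narrowPeak format on the mm10 assembly. There is 1 list for each replicate, 1 for both replicates pooled, and 1 replicated list. Per the deposited notes that accompany the files, each replicate list was made from that replicate's alignments and 2 other files whose role is not stated, the pooled list from the alignments of both replicates and the same 2 files, and the replicated list from the replicate lists and the pooled list. The labels name a possible control experiment. The aligner, the peak caller, their versions and the rule behind the replicated list are not given in the sources used here. Each peak carries an enrichment signal value, −log10 p and −log10 q as the authors' caller gave them, per the narrowPeak file type in the deposited notes. These are the authors' values and were used only to describe, rank or filter peaks within a list. The largest p in any list was 0.0097, and the share of peaks with −log10 q of at least 2 was 95.8% in the replicated list, 75.1% in the pooled list, 58.7% in replicate 1 and 71.6% in replicate 2. The lists therefore hold many weak calls. They give no read counts, so the sequencing depth is unknown and no interval that needs it was computed.

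Genes came from the basic set of GENCODE mouse release M21, whose assembly GRCm38 is mm10, and sequence from the RefSeq copy of the same assembly. The annotation held 21851 protein-coding genes on chromosomes 1 to 19, X and Y, with 41438 transcription start sites (TSSs) of protein-coding transcripts. Y carried 183 of these genes and no peak in any list. A gene was called marked when the window of 1 kb either side of any of its TSSs overlapped a peak of the replicated list by at least 1 bp. The covered share of a gene is the percent of the 5 kb either side of a TSS that lies in peaks, taken at its most covered TSS. Values per replicate came from each replicate's own list and are given as mean ± SD with n = 2. Both replicate lists hold more peaks than the replicated list and a smaller share with −log10 q of at least 2, and a replicate mean can lie above or below the replicated value.

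Observed values were set against circular shifts, in which all peaks of a chromosome were moved together by a random distance of at least 1 Mb, wrapping around between its first and last sequenced base. This permutes positions and keeps the spacing of peaks. The 1000 shifts of the main values give a smallest possible one-sided p of 0.000999, and the 100 shifts of the alternatives 0.0099. The 23 gene lists and 23 gene families were fixed, with the tests, the rule for the genes named and most alternatives, before the data were examined. Each list or family was tested against all other protein-coding genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 23 lists or the 23 families and a threshold of 0.05. An exact test stratified by decile of promoter CpG observed/expected ratio, counted in 500 bp either side of the TSS, was run beside it. The 5 pairs of lists were compared by Fisher's exact test with adjustment over the 5. Covered shares of Hox genes were compared by exact permutation tests, two-sided. Intervals of shares of genes are exact Clopper-Pearson intervals at 95%. Genes, not embryos, are the units of these tests, neighbouring genes are not independent, and the p-values describe these peak lists.

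Every Hox gene was to be summarised by cluster. In each list the 2 marked members with the largest covered share and the 2 unmarked members first in the alphabet were named. In each family past its threshold the member with the largest covered share was named. Genes with a TSS in the 20 longest domains were named, up to 30 genes, and Actb and Gapdh served as controls whatever they showed. Genes outside this rule are said to be so where they appear. Domains were peaks of the replicated list merged within 3 kb.

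Alternatives covered each replicate list alone, the pooled list, a −log10 q of at least 2, the peaks at or above the median enrichment, at least 400 bp of the window covered, windows of 500 and 2500 bp, 1 TSS per gene, the CpG-stratified test, genes thinned to 1 per 100 kb, and merging distances of 1 and 10 kb. Added after the data were seen were the TSSs of the comprehensive annotation, a list of only those replicated peaks overlapped by both replicates, a background without chromosome Y, the CpG deciles in each replicate list, and covered shares in place of marking for 4 pairs of lists (100000 permutations).

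The tests were checked on simulated data over the same 21851 genes. With 75% of list members and 25% of other genes marked, the list test called 94.3% of lists over 100 simulations and 99.8% of lists of 18 or more genes. It called 0.733% of lists marked at the background rate. Each gene was marked independently of its neighbours, so these rates do not cover lists of neighbouring genes. Where CpG content alone set marking, the stratified test called 1.5% of lists and Fisher's test without strata 61% over 200 simulations. There marking rose steadily with CpG and the lists were CpG-rich genes, unlike the data, where marking was highest in decile 5. The 61% therefore does not measure the error of Fisher's test here, and the stratified test was not checked under the observed shape. Randomly placed peaks gave 0.976 times the shifted count of marked genes, and a list with 10000 peaks planted at TSSs gave 7.88 times. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.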

Results

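Peaks of H3K27me3 were examined in whole limbs of mouse embryos at day 15.5, a stage at which cartilage, muscle, tendon, skin and vessels have formed and the digits are separated. The 2 biological replicates were pools of 78 and 62 embryos of both sexes. Replicate 1 gave 90399 peaks over 38.8 Mb and replicate 2 gave 91979 peaks over 44.1 Mb. The replicated list held 42770 peaks with a median width of 490 bp, covering 36.5 Mb, and the pooled list 98953 peaks covering 51.0 Mb. Read depth was unknown, since the lists carry no counts.

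The strongest H3K27me3 regions recurred between the pools, and the weak ones mostly did not. Of the 9040 replicate 1 peaks of lowest p, with a median width of 989 bp, 97.3% overlapped a peak of replicate 2. For the 9198 replicate 2 peaks of lowest p the share was 95.3%. Among the 9039 and 9197 peaks of highest p these shares were 28.2% and 22.3%. Over whole lists, 45196 of 90399 replicate 1 peaks and 40891 of 91979 replicate 2 peaks (44.5%) overlapped the other list by at least 1 bp. Circular shifts gave means of 3.08% and 2.96% (one-sided permutation p = 0.000999 in each direction, the smallest that 1000 shifts can give). The lists shared 38.0% of their joint covered bases.

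All 42770 replicated peaks had the coordinates of a pooled peak and made up 43.2% of the pooled list. Replicate 1 overlapped 89.6% of them, replicate 2 overlapped 92.8%, and both overlapped 82.7%. At 50% of either peak, 34984 replicated peaks (81.8%) were overlapped by both replicates and 7786 were not. The latter were narrower, with a median of 351.5 bp against 548 bp, and together covered 3.02 Mb.

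H3K27me3 was concentrated at promoters. Windows of 1 kb around TSSs took 15.8% of the covered bases, 7.15 times their mean share after circular shifts (2.20%), and exons outside them took 8.62%, 2.37 times. Intergenic sequence took 35.6% against 51.5% in the shifts, and introns 40.0% against 42.6%. The promoter and exon shares exceeded those of all 1000 shifts, and the intergenic share lay below all of them (one-sided permutation p = 0.000999 for each, the smallest possible). The one-sided permutation p for the lower intron share was 0.017, and it was 0.0792 and 0.099 in the lists of replicate 2 and replicate 1 alone.

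Of the 21851 protein-coding genes, 4038 (18.5%) were marked. Shifted peaks marked 872 genes on average and at most 1065, so the observed count was 4.63 times the shifted mean (one-sided permutation p = 0.000999, the smallest possible). The replicate lists marked 4744 and 4839 genes, or 21.9% ± 0.307 (SD, n = 2). They shared 4055 marked genes, which were 85.5% of those of replicate 1 and 83.8% of those of replicate 2. Actb and Gapdh, which encode a cytoskeletal actin and a glycolytic enzyme made in nearly all cells, had no peak within 5 kb of a TSS in the replicated list or either replicate list.

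Promoters of intermediate CpG content were marked most often. The share of marked genes was 2.56% in the lowest decile of CpG observed/expected ratio, reached 36.3% in decile 5 and fell to 13.2% in decile 10. Each replicate list had its highest share in decile 5 as well. The share in decile 5 was 2.75 times that in decile 10, a ratio that was not tested. The ratio of decile 10 to decile 1, which does not bear on the maximum, was 5.16 (Fisher's exact test, two-sided, p = 6.77e-42), and 8.86 with CpG counted over 1 kb either side of the TSS. It was 2.8 and 3.29 in the lists of replicates 1 and 2 alone, where more genes of decile 1 were marked (5.17% and 4.67%).

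**Figure D1:**
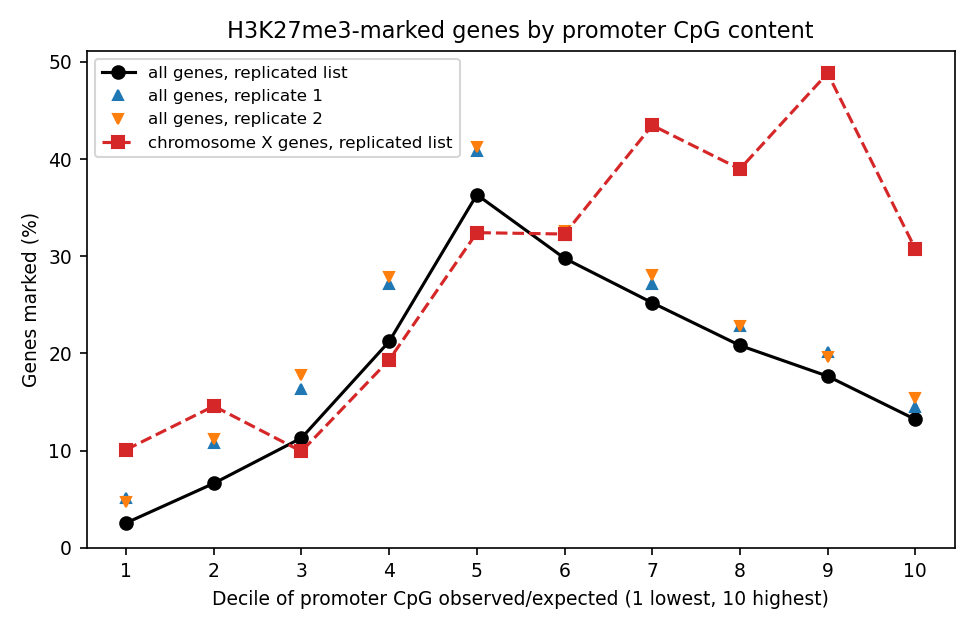
Percent of protein-coding genes marked (vertical axis) by decile of promoter CpG observed/expected ratio (horizontal axis). Black circles are all genes in the replicated list, blue and orange triangles the same genes in the lists of replicates 1 and 2, and red squares the 948 genes of chromosome X in the replicated list. All genes peak in decile 5 at 36.3%, while the X genes stand highest in decile 9, at 48.8% of 43 genes.

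Most regulators of neural, endoderm and heart development carried the mark. Of 56 transcription factors of neural and sensory development, 54 (96.4%) were marked, as were 19 of 22 of endoderm and gut (86.4%) and all 12 of heart. The neural share was the same in each replicate, and the endoderm share was 86.4% in replicate 1 and 90.9% in replicate 2. Neurod2 (chromosome 11, 98325415 to 98329648), a neuronal differentiation factor, and Neurog1, which commits cells to sensory neuron fate, were covered over 100% of the 5 kb either side of the TSS, and 99.0% ± 0.417 and 98.8% ± 0.389 in the replicate lists (SD, n = 2). Cdx2 and Foxa2, regulators of intestine and of endoderm and floor plate, and Tbx1, a regulator of the cardiac outflow tract, were also covered at 100%. Tbx20, which acts in heart chambers, was covered at 97.1%. The unmarked members were Neurod4 (0% covered) and Neurod6 (10.7%) in the neural list, and Hnf1a (15.8%), Hnf4a (0%) and Isx (0%) in the endoderm list. The last of these was chosen after its values were seen, and Hnf1a was marked in replicate 2. Each of the 3 lists was marked more often than other genes (Fisher's exact test, adjusted p = 4.5e-36, 4.49e-11 and 6e-09), and also against genes of the same CpG decile (exact stratified test, adjusted p at most 1.82e-07). The endoderm and heart lists share Gata4, Gata5 and Gata6, all marked and outside the naming rule, so their results are not independent.

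Genes that neurons use late, such as transmitter enzymes, transporters and neurofilaments, were marked nearly as often. Of 22 such genes 21 were marked (95.5%, 95% CI 77.2 to 99.9, exact adjusted p = 5.31e-14). Slc32a1, the vesicular transporter of inhibitory transmitters, was covered at 99.0% and Gad2, a GABA-synthesising enzyme, at 97.5%. Tph2, which makes serotonin in the brain, was the 1 unmarked member, at 0%.

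Regulators of the limb itself were also marked in large part. Each replicate pooled whole limbs, so a peak cannot be assigned to the cells that express a gene. The same holds for the lists of limb cell types and the Hox genes below. Of 31 limb patterning and mesenchyme transcription factors 28 were marked (90.3%, 95% CI 74.2 to 98.0, exact adjusted p = 7.82e-17), and of 29 limb signalling genes 24 (82.8%, 95% CI 64.2 to 94.2, exact adjusted p = 6.16e-13). Lhx2, which acts in the early distal mesenchyme, was covered at 97.7% (91.2% ± 4.47 over replicates, SD, n = 2), and Irx3 at 96.0%. Wnt10b was covered at 99.6% and Shh, the signal of the posterior limb bud margin (chromosome 5, 28456815 to 28467256), at 95.7% (91.1% ± 4.78, SD, n = 2). The unmarked transcription factors were Gli3, the transducer of hedgehog signals, at 0%, Prrx1, a regulator of limb mesenchyme, at 11.9%, and Prrx2 at 0%, the last of these named after its values were seen. Prrx1 was marked in replicate 1 and Prrx2 in replicate 2. Bmp7 and Fgf10, the latter a growth signal of limb mesenchyme, were unmarked signalling genes, with 17.7% and 2.62% covered, though Bmp7 was marked in replicate 2.

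Neural regulators were covered more widely than limb regulators, and a difference in how often they were marked was not resolved. The marked shares of neural and limb transcription factors, 96.4% and 90.3%, were not separated by Fisher's exact test between the lists (adjusted p = 0.572), nor were those of endoderm and limb regulators (86.4% against 90.3%, adjusted p = 0.854). A comparison of covered shares, chosen after the data were seen, gave 85.7% ± 20.3 (SD over 56 genes) for the neural list and 67.6% ± 26.8 (31 genes) for the limb list, a difference of 18.1 points (permutation test, two-sided, adjusted p = 0.00176 over 4 pairs). Both replicate lists showed it, with 20.8 points in replicate 1 and 19.8 in replicate 2. The neuronal terminal genes were covered at 54.9% ± 30.6, which was 30.8 points below the neural transcription factors (permutation test, adjusted p = 0.00016), and 18.8 points below them over 2500 bp either side of the TSS (adjusted p = 0.00685). The marked shares did not separate these lists (exact adjusted p = 1). Endoderm and limb transcription factors, at 73.3% ± 33.3 and 67.6%, did not separate by this measure (permutation test, adjusted p = 0.5).

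Among the muscle genes, most regulators were marked and most genes of the contractile apparatus were not. Of 12 myogenic transcription factors 9 were marked (75%, exact adjusted p = 6.11e-05), against 4 of 20 skeletal muscle structural genes (20%, adjusted p = 0.812). Their CpG deciles gave expected shares of 27.4% and 14.9% (exact stratified test, adjusted p = 0.0024 and 0.727). The tests between these lists below were not adjusted for CpG content. Pax7, the factor of muscle progenitors, was covered at 98.7% (96.9% ± 2.3, SD, n = 2) and Lbx1, which acts in migrating muscle precursors, at 96.0%. Myog, the factor of muscle differentiation, and Mef2c were unmarked, both at 0%. Of the structural genes, Acta1, the skeletal actin, was covered at 73.1% and Des, which encodes desmin, at 46.0%, while Actc1, marked in replicate 2, and Chrna1 stood at 0%. Fisher's exact test between the lists gave an adjusted p of 0.0176, but with each replicate's own list 30% of structural genes were marked and the adjusted p was 0.134 (replicate 1) and 0.0672 (replicate 2). It was 0.121 with TSSs of the comprehensive annotation. By covered share the lists stood at 50.1% ± 43.1 and 7.42% ± 18.7 (permutation test, adjusted p = 0.00176), and the difference passed the threshold with either replicate list.

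The other lists of cell types in the limb fell into a marked and an unmarked part. Of 28 cartilage and bone genes 17 were marked (60.7%, exact adjusted p = 2.02e-06). Runx3 and Dlx6, regulators of skeletal differentiation, were covered at 96.9% and 86.3%, whereas the collagen genes Col10a1 and Col11a1 had 0%. Outside the naming rule and picked after their values were seen, Sox9, the master regulator of cartilage, was unmarked with 19.7% covered, and the cartilage matrix genes Col2a1 and Acan were marked with 46.1% and 66.6%. Of 22 epidermis genes 14 were marked (63.6%, exact adjusted p = 7.9e-06), with Tfap2c at 100% and Tfap2a at 96.3% against Klf4 and Ivl at 0%. Of 18 endothelial genes 10 were marked (55.6%, exact adjusted p = 0.00077), with Sox7 at 96.8% and Flt1, a VEGF receptor gene, at 91.2%, against Cdh5 and Egfl7 at 0%. Of 14 Schwann cell and melanocyte genes 7 were marked (50%, exact adjusted p = 0.0114), with Foxd3 at 90.2% and Sox10 at 72.6% against Cdh19 and Dct at 0%. With genes thinned to 1 per 100 kb the endothelial list kept 12 genes and an adjusted p of 0.0844, and the Schwann cell and melanocyte list 9 genes and an exact adjusted p of 0.559.

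Several lists did not pass the test. Tendon and fibroblast genes were marked at 6 of 18 (33.3%, exact adjusted p = 0.175), with Egr2 covered at 84.2% and Mkx at 39.0%, and the collagen genes Col3a1 and Col5a1 at 0%. Blood cell genes were marked at 5 of 20 (25%, 95% CI 8.66 to 49.1, exact adjusted p = 0.457). They included Gata2 at 100% and Tal1 at 98.9%, regulators of blood stem cells, against Adgre1 at 0% and Alas2, marked in replicate 1, at 9.04%. This list stood at 40% in each replicate list (exact adjusted p = 0.0777 and 0.0893), and reached 50% and an exact adjusted p of 0.0188 with the pooled list. Germline genes were marked at 3 of 18 (exact adjusted p = 1), the highest being Prm1 at 21% and Nanos2 at 15%, while Dazl and Ddx4 had 0%. The 1 marked housekeeping gene of 20 was Pgk1 (chromosome X, 106187100 to 106203699), with 3.25% covered and no overlap at the promoter in replicate 1, while B2m had 0% (exact adjusted p of the list 0.196). In the replicate 1 list, with 0 of the 20 genes marked, housekeeping genes were marked less often than other genes (exact adjusted p = 0.0189).

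A list of Polycomb complex genes, with 2 genes of demethylases that erase the mark, was marked at 8 of 30 (26.7%, exact adjusted p = 0.292). Epop, an accessory subunit, was covered at 75.2% and Cbx8, a reader, at 66.0%, while Aebp2 had 0% and Cbx2, marked in replicate 2, 4.27% (3.44% ± 4.86, SD, n = 2). Cell cycle inhibitors were marked at 4 of 11 (36.4%, exact adjusted p = 0.175). The neighbours Cdkn2b and Cdkn2a on chromosome 4, known Polycomb targets, were covered at 87.2% and 85.0%, and Cdkn1b and Cdkn1c at 0% and 3.8% (6.25% ± 5.33 for Cdkn1c, SD, n = 2). Imprinted genes were marked at 6 of 24 (25%, exact adjusted p = 0.469), with Igf2 at 88.2% and Grb10 at 82.7% against Igf2r at 0%.

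**Figure D2:**
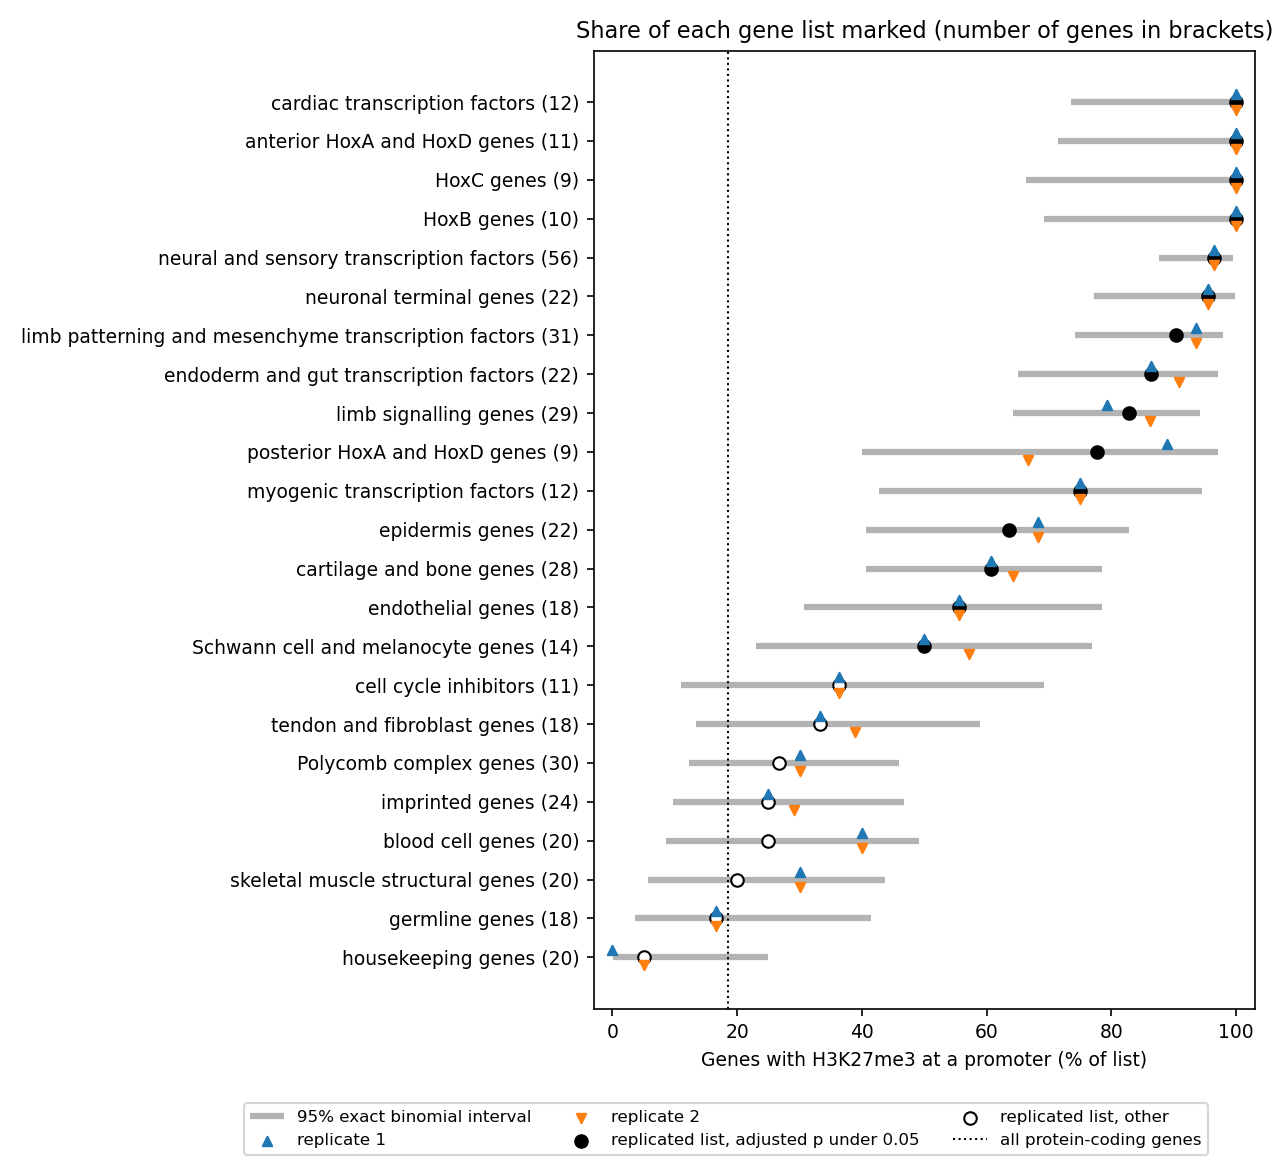
Percent of genes marked by H3K27me3 at a promoter (horizontal axis) in each of the 23 lists (vertical axis, number of genes in brackets). Circles give the replicated list, filled where Benjamini-Hochberg adjusted p was under 0.05, triangles the lists of replicate 1 (blue, up) and replicate 2 (orange, down), grey bars the 95% exact binomial interval and the dotted line the 18.5% of all protein-coding genes. Neural and sensory transcription factors stand at 96.4% and housekeeping genes at 5%.

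Families defined by gene symbol separated in both directions. Members were marked in full for Wnt ligands (19 of 19), Nkx (14 of 14), LIM homeobox (12 of 12), Pax (9 of 9), Irx (6 of 6) and Dlx genes (6 of 6). Hox genes were marked at 37 of 39, T-box genes at 13 of 16, Gata at 5 of 6, Fgf ligands at 15 of 22, Six1 to Six6 at 4 of 6, Fox at 28 of 44, Sox at 12 of 19 and Bmp at 6 of 11. The most covered members were Nkx6-2, Six3, Gata2, Foxa2, Hoxb5 and T, the mesoderm factor brachyury, all at 100%, then Dlx4 at 98.9%, Lhx1 at 98.9%, Fgf8 at 90.2% and Bmp6 at 53.3%. Beyond developmental regulators, 72 of 92 potassium channel genes (78.3%, exact adjusted p = 1.73e-34) and 105 of 361 solute carrier genes (29.1%, adjusted p = 1.27e-06) were marked, with Kcnh3 covered at 96.7% and Slc6a5, the neuronal glycine transporter, at 99.2%. All 16 of these families were marked more often than other genes (Fisher's exact test, adjusted p at most 0.0133). The exact stratified test kept 15 of them, with an adjusted p of 0.0869 for Six1 to Six6.

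Families of the opposite kind were large arrays and constitutive genes. None of 327 vomeronasal receptor genes, 7 of 1092 olfactory receptor genes (0.641%), 20 of 365 Zfp zinc finger genes (5.48%) and 1 of 79 ribosomal protein genes (1.27%) were marked. Whether reads could be placed in these families was not tested, so a lack of peaks there need not be a lack of the mark. With the lists of replicates 1 and 2 alone the olfactory share was 2.84% and 2.11%, and the ribosomal share 3.8% in both. Marks were also few among proteasome subunit genes (2 of 39), keratin-associated protein genes (3 of 57, or 5.26%, and 10.5% in each replicate) and clustered protocadherin genes (3 of 55, or 5.45%, and 10.9% in replicate 2). The most covered members were Zfp536 at 85.9%, Psmb8, an immunoproteasome subunit, at 76.7%, Olfr94 at 47.2%, Rpl18a at 27.8% without a marked promoter, Krtap17-1 at 22.1% and Pcdhga11 at 12%. Every one of the 7 families was marked less often than other genes (exact adjusted p at most 0.0359), and within CpG deciles 6 were, with 0.363 for the keratin-associated genes. The proteasome, keratin-associated and clustered protocadherin calls were also lost with thinned genes (exact adjusted p = 0.0575, 0.221 and 1).

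Along the Hox clusters, which pattern the body and limb axes, cover was highest over HoxC and lowest over HoxA. Peaks covered 93.3% of HoxC (chromosome 15, 102916103 to 103041852), 87.0% of HoxD (chromosome 2, 74663310 to 74770142), 79.8% of HoxB (chromosome 11, 96189316 to 96373256) and 51.7% of HoxA (chromosome 6, 52150590 to 52265880). In replicates 1 and 2 the HoxA values were 45.7% and 47.9%, and those of HoxC 88.0% and 92.7%. All 10 HoxB and 9 HoxC genes were marked, with Hoxb5, Hoxb6 and Hoxc12 covered at 100% and Hoxc4 at 97.4%. All 11 anterior HoxA and HoxD genes were marked too, from Hoxa7 at 34.7% to Hoxd4 at 98.4%, with Hoxd3 at 97.4%. Of the 9 posterior HoxA and HoxD genes, those best known for limb segments, 7 were marked (77.8%). Hoxd9 and Hoxd10 were covered at 83.1% and 79.4%, whereas Hoxa9 had 0% (1.06% ± 1.5, SD, n = 2) and Hoxa11 16.3% (18.6% ± 3.67, SD, n = 2), both unmarked. Hoxa11 was marked in replicate 1. Hoxa10 was marked with 20.4% covered, but 23.6% in replicate 1 and 8.6% in replicate 2, where it was unmarked. Hoxa13 was marked with 39.0% covered. The marked share of the 9 posterior genes was 88.9% in replicate 1 and 66.7% in replicate 2.

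Over all 20 genes the posterior mean was 50.9% ± 32.1 (SD, n = 9) and the anterior mean 75.1% ± 20.6 (n = 11), a difference that missed the threshold (exact permutation test, two-sided, p = 0.0601). It passed with either replicate alone, with an exact p of 0.0271 in replicate 1 and 0.0201 in replicate 2. The windows of neighbouring Hox genes overlap in part, so the genes are not independent units of these tests. The marked shares of posterior and all other Hox genes, 77.8% and 100%, gave an exact adjusted p of 0.121, and 0.046 with replicate 2 alone. As lists, the 4 Hox groups exceeded other genes (exact test, adjusted p at most 0.000328), but each lies in 1 or 2 clusters, and thinning to 1 gene per 100 kb left too few members for a call (exact adjusted p from 0.11 to 0.352).

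**Figure D3:**
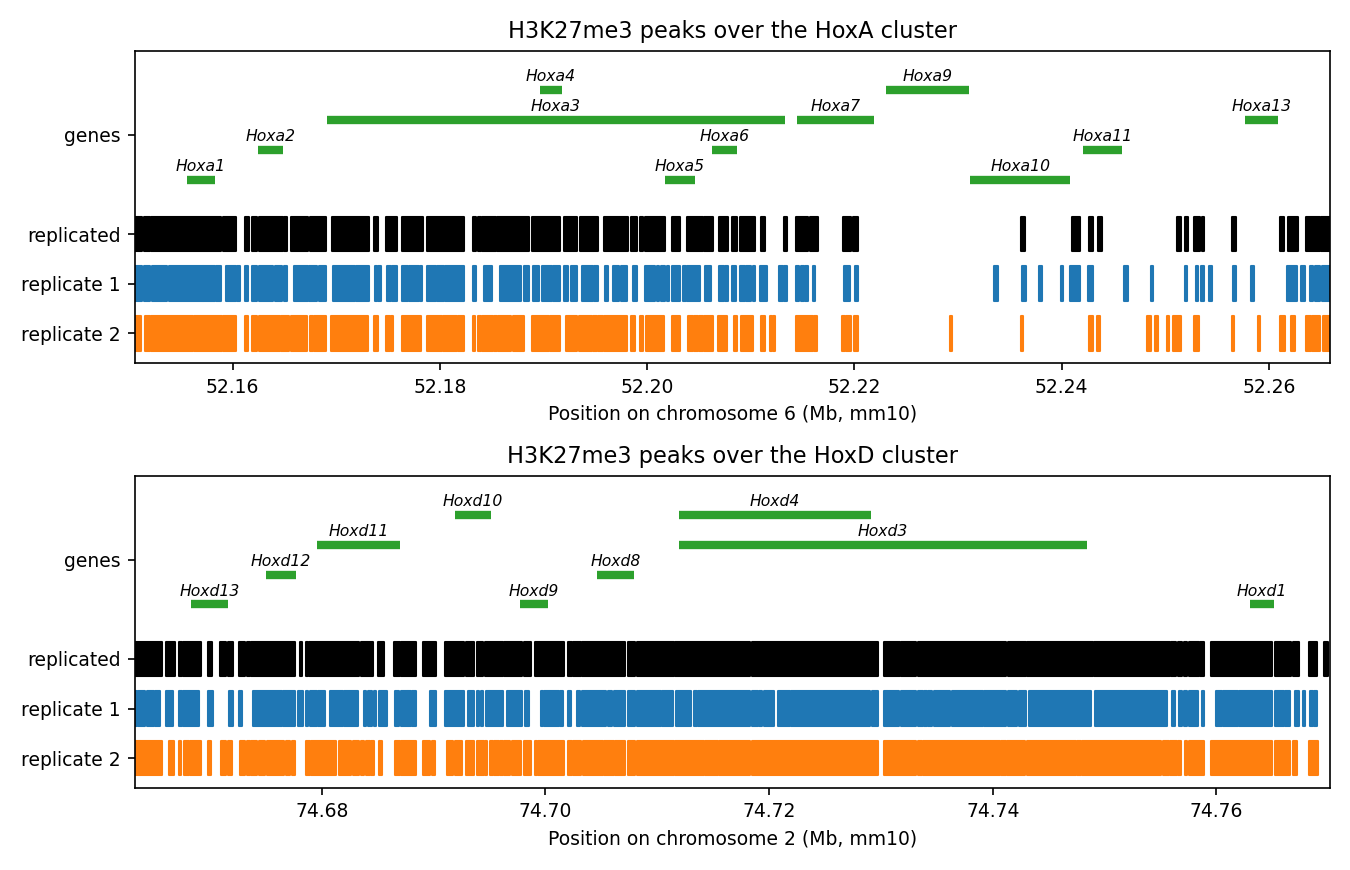
Peaks over the HoxA cluster (top) and the HoxD cluster (bottom) by position in mm10 (horizontal axis, Mb). Black, blue and orange bars are the replicated list and the lists of replicates 1 and 2, and green bars are the annotated gene extents. Anterior HoxA genes range from 34.7% at Hoxa7 to 85.9% at Hoxa1 and posterior HoxA genes have a mean covered share of 18.9%, while HoxD genes range from 69.6% at Hoxd13 to 98.4% at Hoxd4.

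Merging peaks within 3 kb gave 16012 domains, of which 407 were at least 20 kb long. The longest, of 181128 bp, held all 9 HoxC genes (chromosome 15, 102895658 to 103076785), followed by 134818 bp over Hoxb1 to Hoxb9, 133711 bp at Rhcg and the microRNA gene Mir9-3 on chromosome 7, 124928 bp from Evx2 to Hoxd1 and 104342 bp at Pax7. Rhcg, an ammonium transporter gene, was covered at 64.9% and Evx2, a homeobox gene beside HoxD, at 74.5%. Others of the 20 longest held Irx3, Hoxb13 and Hoxa1 to Hoxa7 and, beyond the limit of the naming rule, the neural regulators Zic1, Zic4, Lhx5 and Dmbx1, the forkhead genes Foxd2 and Foxe3, and the cadherin gene Cdh22. The remaining 7 of the 20 had no protein-coding TSS inside, the longest of them a stretch of 102920 bp on chromosome X (99149770 to 99252689) with 50.9% of its length covered. The number of long domains depended on how peaks were joined, with 179 at a merging distance of 1 kb and 1045 at 10 kb, and was 520 and 628 in replicates 1 and 2.

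Chromosome X carried more and narrower peaks than the autosomes. It held 28.7 replicated peaks per Mb against 15.8 over the autosomes, with a median width of 412 bp against 503 bp. Its covered length was 14.95 kb per Mb against 14.1, a ratio of 1.06, below the 24.3 of chromosome 11. The ratio was 1.3 in replicate 1 and 1.09 in replicate 2. Of 948 X-linked genes 233 were marked (24.6%), against 18.4% of 20720 autosomal genes (Fisher's exact test, two-sided, p = 3.19e-06). Single autosomes ranged from 14.14% on chromosome 14 to 24.97% on chromosome 15, which lay above X. The test takes the autosomes together and ignores this spread, so its p does not show X to be unusual among chromosomes. The X share was 33.3% and 32.2% in the replicate lists, against 21.4% and 21.9% on the autosomes. There it lay above the highest single autosome, chromosome 15, at 29.07% in both lists. Circular shifts of the same peaks gave 6.03% on X and 3.93% on the autosomes. No gene of chromosome Y was marked, and no list has a peak there. Whether reads could be placed on Y, or peaks there were removed, was not tested, so this need not be a lack of the mark.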

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

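Of 812 alternative values over 68 results, 772 kept their direction and their side of the threshold (for values with no test, stayed within 1.5 times or the replicate spread) and none reversed. List and family values made up 644 of the 812. Many settings share most of their peaks and genes, so the tally does not count independent checks. The tests on the comprehensive TSSs, on doubly overlapped peaks, on genes without chromosome Y, on covered shares and on CpG deciles by replicate were chosen after the data were seen. No paired analysis was possible because the series has 1 group. The cause of the changes below was not tested, except that thinning leaves fewer genes. Depth was unknown and its effect could not be assessed.

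Replicate overlap was 40.9% and 32.7% at 50% of the query peak, 65.4% and 54.8% among the 20000 peaks of lowest p, and 56.3% and 40.8% among peaks with −log10 q of at least 2. The decile 10 to decile 1 ratio was 8.86 with 1 kb windows and 2.8 to 3.29 without a replicate. Marked genes numbered from 3423, for peaks at or above the median enrichment, to 5065, for the pooled list. Leaving out either replicate gave 0 to 1 lists marked below other genes, that 1 being housekeeping genes (0% to 5% marked, exact adjusted p = 0.0189 without replicate 2). Blood cell genes reached 50% with the pooled list (exact adjusted p = 0.0188).

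Thinning to 1 gene per 100 kb left 9 lists above other genes. It ended the calls of endothelial genes (50%), Schwann cell and melanocyte genes (33.3%), and posterior and anterior HoxA and HoxD, HoxB and HoxC genes (100% each). It left 4 families below other genes, ending those of proteasome (0%), keratin-associated (0%) and clustered protocadherin genes (20%), and ended that of Six1 to Six6 (100%). The Six1 to Six6 (66.7%, exact adjusted p = 0.0869) and keratin-associated (5.26%, 0.363) calls were lost within CpG deciles, and the latter also with the pooled list (12.3%, 0.0581). The proteasome call was lost at 5.13% with the stronger peaks, 400 bp covered, 500 bp windows and 1 TSS per gene (exact adjusted p from 0.0529 to 0.0773), and at 10.3% with comprehensive TSSs.

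The difference between myogenic factors and muscle structural genes was 45 points with each replicate left out and 45 with comprehensive TSSs, past the threshold in none of these. Posterior minus other Hox genes ranged from -33.3 to -11.1 points without a replicate, and posterior minus anterior Hox covered share from -29.1 to -24.2, passing the threshold with each replicate left out. Covered shares of neural transcription factors and neuronal terminal genes stood 18.8 points apart over 2500 bp either side of the TSS, against 30.8 over 5 kb. Long domains numbered 179 and 1045 at 1 and 10 kb, and 520 to 628 without a replicate. The X excess ranged from 3.56 to 13.4 points over 11 alternatives, each past the threshold, and the lower end came from the peaks at or above the median enrichment.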

Other observations

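Long domains held most members of some marked families and few of others, in a count chosen after the data were seen. Of 407 domains of at least 20 kb, 288 held a TSS of a protein-coding gene and 119 (29.2%) held none. The 385 genes with a TSS inside made up 1.76% of all genes. They included 35 of 39 Hox, 5 of 6 Irx, 7 of 9 Pax, 9 of 12 LIM homeobox, 8 of 14 Nkx and 17 of 44 Fox genes, each above other genes (Fisher's exact test, Benjamini-Hochberg over 23 families, adjusted p at most 3.22e-08). Six1 to Six6, Dlx and Gata genes had 4 of 6 each (exact adjusted p = 2.65e-06). Wnt ligands had 6 of 19, T-box 6 of 16 and Sox genes 4 of 19 (exact adjusted p at most 0.000528). Neighbouring genes can share a domain, as all 9 HoxC genes did, so genes are not independent units here or for the lists below. No thinned count was made. Potassium channel genes, of which 72 of 92 were marked, had 3 of 92 in long domains (exact adjusted p = 0.299) and solute carrier genes 5 of 361 (exact adjusted p = 0.918). Fgf ligands had 1 of 22 and Bmp genes 0 of 11.

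Among the lists, which like the families were tested only against other genes, shares also varied. Of 56 neural and sensory transcription factors 36 (64.3%) had a TSS in a long domain, and of 31 limb transcription factors 18 (58.1%), while the count was 3 of 22 for neuronal terminal genes (13.6%, each list above other genes, exact adjusted p over 23 lists at most 0.0125). Limb signalling genes had 6 of 29 and cartilage and bone genes 4 of 28. The skeletal muscle structural, tendon and fibroblast, endothelial, germline and housekeeping lists had 0 members in one, which their sizes of 18 to 20 genes do not separate from the 1.76% of all genes (exact adjusted p = 1 for each).

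In the patterns below, the tests of pooled cover and of the caller's threshold at posterior HoxA were chosen after related values had been seen, and the other tests were written down after the patterns but before their own results were computed. The series has 1 group, so no biological explanation was tested. The share of marked X genes exceeded the autosomal share in CpG deciles 1 and 2 (10.1% and 14.6% against 2.24% and 6.37%) and 6 to 10 (32.3%, 43.5%, 39.0%, 48.8% and 30.8% against 29.7%, 24.6%, 20.3%, 17.1% and 13%) and lay below it in deciles 3 to 5 (9.92%, 19.3% and 32.4% against 12%, 21.5% and 36.9%). CpG content did not account for the X excess, since X genes stood 4.9 points above the share expected from their deciles (exact stratified test, p = 8.62e-05). Chance calls spread over X do not account for it in points, since the X share lay 4.11 points further above its shifted level than the autosomal share (SD 1.67 over 1000 shifts), although as a multiple of the shifted level X stood lower, at 4.08 against 4.67. Whether X holds more chance calls could not be decided, as recurrence above shifts differed from that of autosomal peaks of like rank by -1.68 points on average (SD 7.67 over 20 bins of rank, the smallest with 14 X peaks), with means of opposite sign in replicates 1 and 2 (-5 and 1.65), -11.1 and -10.8 in their strongest bins and 0.0747 and 8.93 in their weakest. The sex of the embryos, mixed in each pool, stays untested and would need pools of each sex.

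The maximum of marking at intermediate CpG content was weighed against a pair of technical explanations. A mismatch between the TSS used for CpG and the TSS that is marked predicts no maximum among genes with a single TSS, but there decile 5 exceeded decile 10 by 22.6 points (36.2% against 13.7%). A general loss of reads at CpG-rich promoters predicts few marked developmental regulators there, but 97.3% of 37 neural, endoderm, cardiac and limb transcription factors in deciles 8 to 10 were marked, against 91.5% of 47 in deciles 4 to 6. Their covered share within 1 kb was 91.6% ± 22.2 and 87.8% ± 27.9. These genes are strongly marked, so a smaller loss at weakly marked promoters remains possible.

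Posterior HoxA genes were less covered than posterior HoxD genes, a comparison noticed in the data. Means were 18.9% ± 16.0 (SD, 4 genes) and 76.5% ± 5.04 (5 genes), and all HoxA values lay below all HoxD values (exact permutation test, two-sided, p = 0.0159, the smallest these counts allow, on neighbouring genes that are not independent). In the pooled list posterior HoxA stayed 51.0 points below the replicated cover of posterior HoxD, which argues against the requirement that a peak be replicated as the whole cause. Signal below the threshold of the peak caller stays open, since the lowest −log10 p of the replicated and pooled lists differs by 0. Repeat-masked sequence was 13.6% ± 1.86 around posterior HoxA TSSs and 14.9% ± 2.86 around those of HoxD (1 TSS per gene), a difference of -1.3 points. This argues against repeat content as the cause. Whether reads could be placed there was not measured.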
